A study of Homo sapiens with 6 samples.

How the data were processed

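RNA of 6 cell cultures was hybridised to 6 arrays, 3 of LS-3B cells and 3 of LS-Par cells. The labels describe LS-3B as highly metastatic and LS-Par as mildly metastatic, and the series design describes the 3 samples of each group as independent. Per the labels, subconfluent cells were harvested, total RNA was extracted with a Bio-Rad Aurum kit and labelled with Cy3 by Agilent's standard protocol. Groups and replicate numbers were taken from the sample titles.

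The authors deposited 1 scanner output file per array. Per the submitters' processing notes, spots were quantified with Agilent Feature Extraction 11.0.1.1, and per the file headers the arrays were read in 1 colour channel and belong to a custom design annotated on genome build hg19. The deposited processed signal is an intensity per spot on a linear scale, after background subtraction and spatial detrending within the array, in which very dim spots carry a small positive surrogate value. The deposited median signal and median local background are raw pixel intensities. The deposited flags, given as other values of 0 or 1, mark spots that are well above background, saturated or outliers. Any normalization between arrays by the authors is not given in the sources used here.

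Each file held 62903 spots. Left out of the tests were 1439 spots with a control type and 360 spots named as negative controls. The remaining 60924 probes were 60904 probes known only by the array maker's identifier, each with its own intensity and no gene name, and 20 probes that carry a RefSeq accession and are printed as 10 spots each. All 20 accessions matched a gene symbol in the RefSeq gene table of assembly GRCh38.p14, and 2 of these genes are not reported here. That table's coordinates were not used, because its build differs from that of the arrays. The other probes were not linked to genes, to a transcript class or to a position here, so counts below are of probes, and several probes may belong to 1 gene. The planned counts of long non-coding RNAs, the tests of 26 gene lists and the comparison of several probes of 1 gene were therefore not run. Of the members of those lists, GAPDH and PGK1 of the glycolysis list were the only ones named on the arrays.

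The log2 of the processed signal was taken, flagged outlier spots (24 to 38 per array) were removed, spots of 1 probe were averaged, and each array's 75th percentile over these probes was subtracted. No spot of these probes was saturated. A probe counted as well above background on an array when most of its spots without an outlier flag carried that flag, and the 33704 probes that were well above background on all 3 arrays of at least 1 group were kept. LS-3B was compared with LS-Par with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with group as the only term and Benjamini-Hochberg adjustment over all kept probes. The threshold was an adjusted p of 0.05, and changes of at least 2-fold were counted separately. Where a probe was not well above background on any array of 1 group, the fold is given as a lower bound, from the mean of the bright group and, on each array of the dim group, the higher of the probe's own value and the lowest value among probes well above background. This bound carries no error, and a stricter detection limit would give a smaller fold. The number of arrays limits the precision. Data simulated for LS-3B against LS-Par had 33641 probes with the spreads of these arrays, independent noise and 200 changed probes. In them the test recovered 38% of probes changed 2-fold and 88% of those changed 4-fold, with 6 false calls among 132. The real arrays share variation across probes and have more probes past the threshold, so these rates may not carry over.

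The rule for the features named in the text was set before the data were examined: the most changed genes with an official symbol, the most changed long non-coding RNAs, the most changed members of each gene list, and a fixed set of further genes. Because 20 genes are named on the arrays, it could be applied in part. None of the 17 reported genes that could be tested passed the threshold, and none of the fixed set is named on the arrays. The text gives the 18 genes and the 2 highest and 2 lowest changed probes without a name, among those past the threshold whose groups did not overlap. These were ranked by the bound where a probe was not well above background on any array of 1 group, and otherwise by the fitted fold. ASHGV40038419, detected on 1 LS-Par array, was thus ranked by a fold that rests partly on background.

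The header gives the same scan for all 6 arrays, so scan could not be a block. The position code in the header was read as row and column on a slide; the files do not define the code or say whether the arrays shared 1 slide. On this reading LS-Par replicates 1 and 2 lay in a row without LS-3B arrays, and LS-Par replicate 3 in a row with all 3 LS-3B arrays. Whether the replicate numbers pair the arrays is not known. Deviations from the group means correlated at -0.09, 0.13 and 0.46 between arrays of the same number, which does not decide it. The alternatives tried were quantile normalization, a percentile over detected probes, no filter and a stricter filter on dim probes, the replicate number as a block, an intensity trend in eBayes with robust estimation, and leaving out each array. Added after seeing the data were normexp background correction (offset 50) on the median signals in place of the mean signals that had been planned, the same offset added to the processed signal, the slide row as a block, the mixed slide row alone, and the ratio of the PGK1 3′ to 5′ control probes as a covariate.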

Results

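Transcripts were measured on 1-colour arrays in a pair of human colon cancer cell populations that differ in metastatic behaviour. LS-Par cells are described as mildly metastatic and LS-3B cells as highly metastatic, and the series concerns selection in vivo and long non-coding RNAs in colon to liver metastasis. Each population was represented by 3 arrays. Between 54.4% and 60.9% of the 60924 probes were well above background on an array, and the 75th percentile of intensity lay between 145 and 172 units. Arrays of the same population correlated at r = 0.988 to 0.995 over the 30700 probes detected on all arrays, and arrays of different populations at r = 0.979 to 0.989. These correlations are across probes, which are not independent replicates.

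The single comparison of the design asks which transcripts differ between LS-3B and LS-Par cells. Each degree of metastatic behaviour is represented by a single population. A difference can therefore not be assigned to metastatic behaviour as against any other difference between these populations. LS-3B and LS-Par cells differed in 1801 of 33704 tested probes (5.34%) at an adjusted p under 0.05 in limma. Of these, 863 were higher and 938 were lower in LS-3B. On the processed signal, a difference of at least 2-fold was seen in 565 higher and 644 lower probes. These counts depend on how dim signals are treated, and with normexp background correction, which adds an offset, they were 272 and 219. Which direction holds more probes also depends on the setting, since more were higher than lower in 6 of 17 alternatives. Among these, normexp and the plain offset shrink differences of dim probes and the stricter filter leaves them out, so their turn says little. More were also higher with quantile normalization (935 against 927), without LS-3B replicate 2 (909 against 854) and without LS-Par replicate 3 (749 against 672). The median log2 fold change of all tested probes was -0.02, and its 5th and 95th percentiles were -0.62 and 0.52. The median SD between replicate arrays was 0.20 in LS-3B and 0.19 in LS-Par on the log2 scale. The values of the populations did not overlap in 20.1% of tested probes, where chance gives 10% for 3 arrays against 3. That 10% is for probes chosen without regard to group. The filter kept 2347 probes through LS-Par alone and 657 through LS-3B alone, which favours no overlap, so part of the excess may come from the filter.

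**Figure D1:**
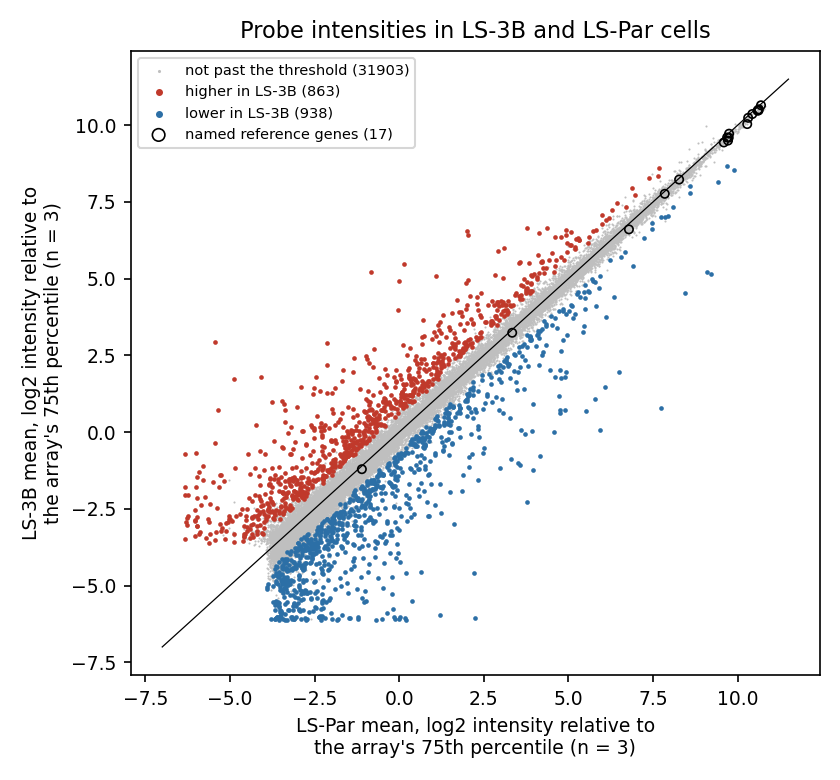
Mean log2 intensity of 33704 probes in LS-Par cells (x axis) and LS-3B cells (y axis), each relative to the array's 75th percentile and averaged over 3 arrays, with the line of equal values. Red and blue points mark the 863 probes higher and the 938 probes lower in LS-3B, and open circles mark 17 tested reference genes, which lie along the line.

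A small set of probes was bright in one population and near background in the other. By the fitted values, 30 probes past the threshold were at least 16-fold higher in LS-3B and 53 were at least 16-fold lower. By the scanner flag, LS-Par cells were not well above background on any array in 85 of the higher probes, and LS-3B cells in 264 of the lower probes. This contrast depends on the flag: in a comparison added after these counts were seen, with 1 intensity threshold for all arrays, 116 higher and 208 lower probes were above it in 1 population alone. For the probes not well above background by the flag the fold is a lower bound, which for 3 of the lower probes includes no difference, and the bound itself reached 16-fold for 3 higher and 8 lower probes.

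On the processed signal, probe ASHGV40018120 was at least 124-fold higher in LS-3B, by the bound set at the lowest detected values of the LS-Par arrays. Its log2 level was 2.93 ± 0.14 (SD, n = 3) in LS-3B and -5.45 ± 0.58 (n = 3) in LS-Par, where it was not well above background (limma adjusted p = 4.6e-06). With normexp, whose offset shrinks differences of dim probes, its log2 difference was 4.39. Probe ASHGV40038419 was well above background on 1 of the 3 LS-Par arrays. It was 1.73 ± 0.09 in LS-3B and -4.88 ± 1.22 in LS-Par (limma adjusted p = 0.00024), where the mean rests on background on the other arrays and so gives no exact fold, and its log2 difference with normexp was 3.11. Among probes lower in LS-3B, ASHGV40055233 was detected on all arrays of both populations, at 0.79 ± 0.18 in LS-3B and 7.75 ± 0.18 in LS-Par. Its log2 difference was -6.96 with a standard error of 0.16 (limma adjusted p = 1.4e-06), a 124-fold lower level in LS-3B. On the processed signal, probe ASHGV40038206 was at least 67.2-fold lower in LS-3B, by a bound set in the same way on the LS-3B arrays. It was not well above background in LS-3B, at -6.07 ± 0.20 against 2.24 ± 0.28 in LS-Par (limma adjusted p = 1.4e-06). Its log2 difference with normexp was -3.82.

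Of the genes named on the arrays, most of them widely expressed reference genes, 18 are reported. Of the 17 that could be tested between the populations, 0 had an adjusted p under 0.05 in limma, 0 when adjusted over the list alone, and 0 an unadjusted p under 0.05. Their log2 fold changes ran from -0.25 to -0.02, with a median of -0.11. The lowest bound among the 95% intervals was -0.56 and the highest was 0.40, so a 2-fold change lay outside every interval. In all 17 the LS-3B mean was the lower one, but this held for 11 of 17 after quantile normalization, so the common direction depends on the scaling.

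None of the named cytoskeletal genes passed the test. ACTB, cytoplasmic beta-actin, had a log2 fold change of -0.07 (95% interval -0.36 to 0.22), ACTG1, its gamma counterpart, of -0.04 (-0.33 to 0.25), and PFN1, the actin-binding protein profilin, of -0.14 (-0.50 to 0.22). ACTB and ACTG1 are close in sequence, and cross-hybridisation between them was not tested. ARHGDIA, a GDP dissociation inhibitor, had a value of -0.08, and DYNLL1, a dynein light chain, of -0.02.

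None of the genes of protein synthesis passed it either. The ribosomal protein genes RPS18, RPLP1 and RPL10 had log2 fold changes of -0.11, -0.14 and -0.11. The RPL10 probe was dim, at a mean log2 level of -1.21 in LS-3B and -1.10 in LS-Par against 10.5 and 10.6 for RPS18. Whether the RPL10 probe reports the full level of its transcript was not tested. RACK1, a ribosome-associated scaffold protein, had -0.07, and EIF3D, a subunit of a translation initiation factor, had -0.09 (-0.51 to 0.34).

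The 2 named members of the glycolysis list were GAPDH, at -0.11 (-0.42 to 0.20), and PGK1, at -0.10 (-0.50 to 0.30). The PGK1 probe was much dimmer, at a mean log2 level of 3.24 in LS-3B and 3.34 in LS-Par against 10.47 and 10.59 for GAPDH. It was lowest, at 2.92, on LS-3B replicate 2. The 3′ control probe of PGK1 was bright, at a mean log2 intensity before scaling of 16.19 in LS-3B and 16.25 in LS-Par. That of GAPDH was at 17.08 and 17.18, and the 5′ control probe of PGK1 at 10.56 and 10.57. These values argue against the dim named PGK1 probe reporting the full level of the transcript. COX4I1, a subunit of mitochondrial cytochrome c oxidase, had the lowest value, -0.25 (-0.56 to 0.07, limma adjusted p = 0.51). MTX1, a mitochondrial outer membrane import protein, had -0.18. Of the remaining genes, PRMT1, an arginine methyltransferase, had -0.22 (-0.54 to 0.10), H3-3A, which encodes histone H3.3, had -0.15, and ODC1, the first enzyme of polyamine synthesis, had -0.04 (-0.48 to 0.40). GRM4, a glutamate receptor gene, was well above background on 3 of the 6 arrays, which were not all of 1 population, and was not tested. Its log2 levels were -3.65, -3.49 and -3.60 in LS-3B and -4.15, -4.06 and -4.05 in LS-Par.

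**Figure D2:**
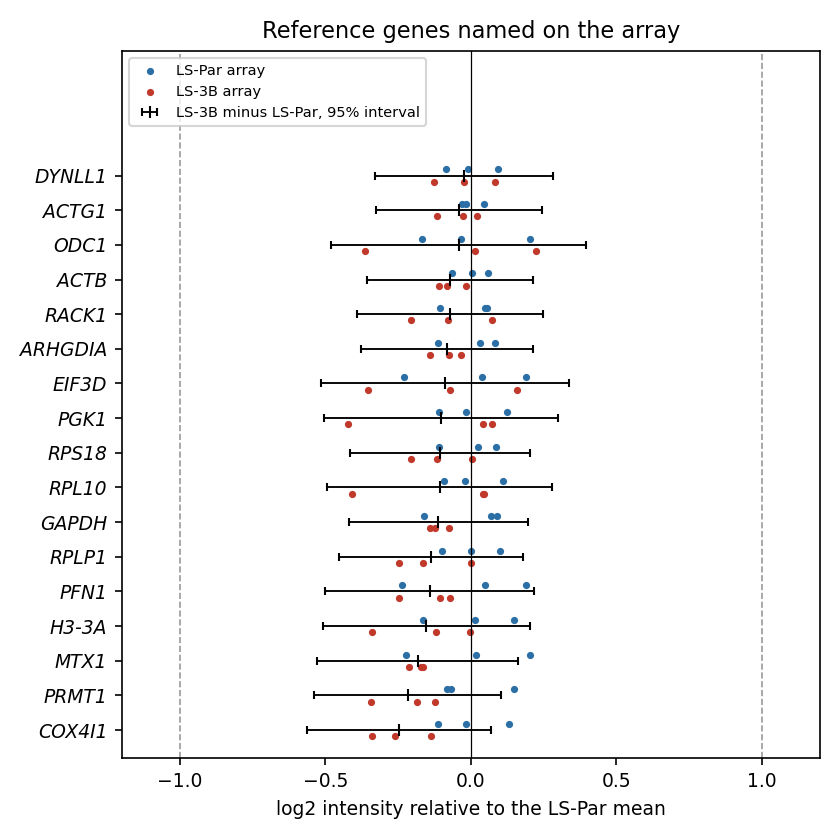
Reference genes named on the arrays: log2 intensity of each array relative to the LS-Par mean (points, 3 LS-3B and 3 LS-Par arrays) and the LS-3B minus LS-Par difference with its 95% limma interval (black bars), with dashed lines at a 2-fold change. All 17 intervals include 0 and lie within the dashed lines.

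The arrays also varied along a direction that crossed the populations. The first principal component of the 30700 probes detected on all arrays held 44.7% of the variance and separated LS-3B from LS-Par, and the second held 31.7%. On the second, LS-3B replicate 2 was at -40.1 and LS-Par replicates 1 and 2 at -23.3 and -20.8, whereas LS-3B replicate 3 was at 39.7, LS-Par replicate 3 at 36.5 and LS-3B replicate 1 at 8.14. The ratio of 3′ to 5′ control probes of PGK1, a measure of how far labelling reached from the 3′ end, ranged from 41.0 to 62.6 over the arrays. Its log2 mean was 5.62 ± 0.31 in LS-3B and 5.68 ± 0.30 in LS-Par (SD, n = 3 each; exact two-sided permutation p = 1, with 0.1 the smallest possible).

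**Figure D3:**
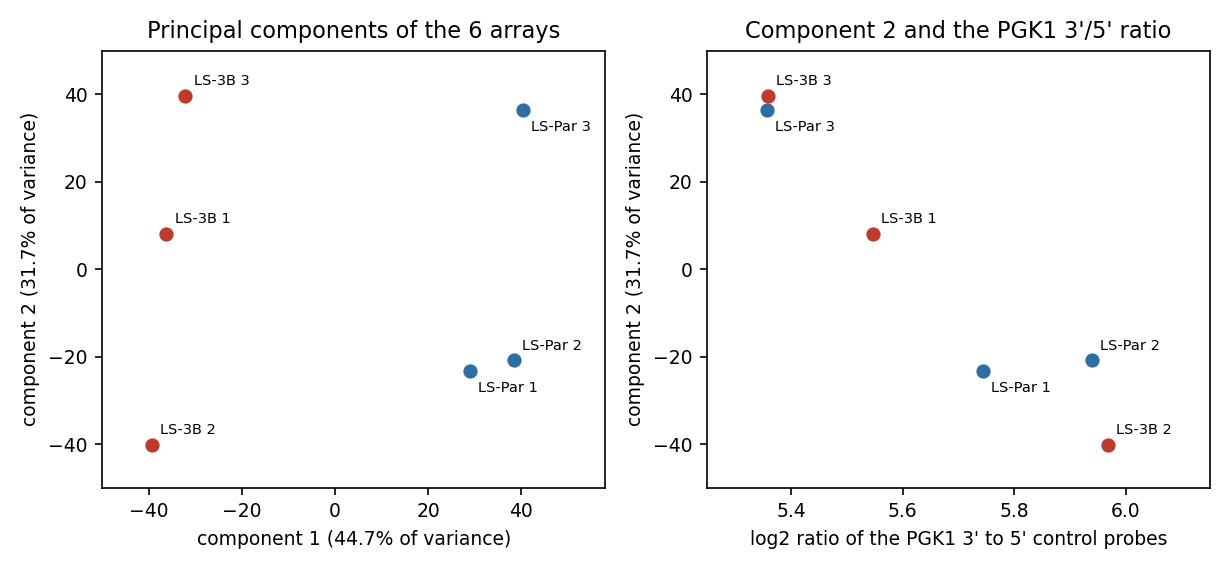
First and second principal components of the 6 arrays (left) and the second component against the log2 ratio of the PGK1 3′ and 5′ control probes (right), with LS-3B arrays in red and LS-Par arrays in blue. The first component separates the populations, and the second runs from -40.1 to 39.7 within LS-3B alone and is lowest on LS-3B replicate 2, the array with the highest ratio.

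Leaving out 1 array at a time gave 532 to 909 probes higher and 637 to 854 lower, and the lowest count of higher probes was that without LS-3B replicate 1. The count of higher probes was 567 without LS-Par replicate 1. With the slide row, as read from the header's position code, as a block, 470 probes were higher and 671 lower. This contrast rests on LS-Par replicate 3, the only LS-Par array in the row that holds both populations. Its folds equal those within that row alone (3 LS-3B arrays and 1 LS-Par array), such as a log2 fold change of -7.09 for ASHGV40055233. None of the 1801 probes turned its direction under any of these settings. They were called on the same arrays, so a kept direction could hardly fail and says little about how well the calls hold.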

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

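The normexp, offset, slide row, mixed row and PGK1 ratio settings were chosen after the data were seen. Of the 1801 probes past the threshold, 0 turned direction under any of the 17 alternatives among those still tested. They were called on the same arrays, and some settings, such as the filters and the intensity trend, leave the fold unchanged. The 0 was thus nearly fixed beforehand and says little about how well the calls hold. Counts moved by over 1.5 times in these cases. With normexp, 272 probes were at least 2-fold higher and 219 at least 2-fold lower in LS-3B. With only the offset of 50 added to the processed signal, they were 287 and 227. All calls were 827 higher and 700 lower with normexp, and 845 and 709 with the offset. Normexp also lowered the log2 differences of 3 probes named in the text, to 4.39 for ASHGV40018120, 3.11 for ASHGV40038419 and -3.82 for ASHGV40038206, and the offset alone gave 4.54, 3.34 and -3.93. Without a filter on dim probes, 550 were higher, with 60924 probes tested. With only probes well above background on all 6 arrays, 709 were higher and 574 lower, and 422 were at least 2-fold higher and 323 at least 2-fold lower, as probes at background in either population are then left out. With the slide row (as read from the header's position code) as a block 470 were higher, and in the mixed row alone 332 were higher and 450 lower, all of them at least 2-fold, from 4 arrays with a lone LS-Par array assumed to vary like LS-3B. More probes were higher than lower in 6 of the 17 alternatives, against the main fit, and more at least 2-fold higher than lower in 4. Both sets include normexp, the offset and the stricter filter, which shrink or leave out dim probes, so their turn was largely fixed beforehand. Leaving out 1 array gave 532 to 909 higher, 637 to 854 lower, 489 to 602 at least 2-fold higher and 541 to 664 at least 2-fold lower. Quantile normalization, the other percentile, the intensity trend and the PGK1 ratio kept all 4 counts within 1.5 times. So did the replicate block, with 887 higher and 926 lower; it shared 1601 calls with the unblocked fit and changed no call of a named gene. Of 289 values of the 17 reference genes under these settings, 0 passed the threshold (smallest adjusted p 0.286), and 22 turned sign, to values of 0.119 or less. Quantile normalization turned RACK1 to 0.0205, ODC1 to 0.0105, GAPDH to 0.0099, DYNLL1 to 0.049, ACTB to 0.0033 and ACTG1 to 0.0199. The slide row as a block, and the mixed row alone, turned MTX1 to 0.039, GAPDH to 0.048, ARHGDIA to 0.032 and PFN1 to 0.095; the cause was not tested. Leaving out 1 array gave ranges of -0.21 to 0.045 for EIF3D, -0.18 to 0.12 for ODC1, -0.18 to 0.044 for RPL10, -0.076 to 0.0297 for DYNLL1 and -0.19 to 0.058 for PGK1. The slide as a block and the mean of several probes of 1 gene were not run. The folds of the 85 higher and 264 lower probes without signal above background in 1 population are bounds.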

Other observations

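The tests of the second component were chosen after the result was seen; those of detection were set before their values were seen, except its comparison with mixed splits. Control probes named for mouse genes gave signal in both populations. Probes named for rat GAPDH and PGK1 were also bright enough to test, so signal on the mouse probes does not by itself show mouse RNA. The mouse GAPDH 3′ probe differed from the human one by -5.84 ± 0.21 log2 units in LS-3B and by -5.55 ± 0.26 in LS-Par (SD, n = 3 each; exact two-sided permutation p = 0.3, with 0.1 the smallest possible). For the PGK1 3′ probes the difference was -4.74 ± 0.04 in LS-3B and -4.73 ± 0.03 in LS-Par (exact permutation p = 1). Of 67 control probes, 24 were bright enough to test and 0 passed the threshold in limma.

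Only 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave 1801 probes past the threshold. The highest of the other splits gave 0, and 10 splits are too few for a share under 0.05. The other splits also used the filter built on the real groups and held the population difference within their groups. Low counts in them follow from any such difference, whatever its cause, so the 0 does not measure chance.

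The second principal component, with 31.7% of the variance, set arrays of both populations apart in the same way. The slide row, as read from the header's position code, is argued against as its only source, since the 4 arrays of the row that holds both populations spanned the whole range of the 6 arrays (a ratio of ranges of 1). A contribution of the row stays open. Within LS-Par, replicates 1 and 2 of the other row were at -23.3 and -20.8, and replicate 3 of the mixed row was at 36.5. The component fell as the log2 ratio of PGK1 3′ to 5′ control probes rose, with Pearson r = -0.965 (exact permutation p = 0.0181, adjusted 0.0222) and Spearman rho = -0.886 (exact permutation p = 0.0333, adjusted 0.0666), and with r = -0.999 without LS-3B replicate 2 and LS-Par replicate 2. The GAPDH ratio gave r = -0.849 (exact permutation p = 0.0222, adjusted 0.0222), rho = -0.771 (exact permutation p = 0.103) and r = -0.885 without LS-Par replicate 3 and LS-3B replicate 2; these 2 relations were computed, and rows or populations hold too few arrays for values of their own. A candidate explanation is a difference between RNA extracts or labelling reactions in how far labelling reached from the 3′ end, while a difference between cultures stays open and untested. With the PGK1 ratio as a covariate 2391 probes passed the threshold in place of 1801, 1769 of them shared. A covariate that follows this component and is balanced between the populations would tend to raise the count under either explanation. The rise therefore does not tell them apart.

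More probes were well above background in LS-Par alone (476, on all 3 arrays against none of LS-3B) than in LS-3B alone (94), a ratio of 5.06. Part of this may come from array noise, since the negative controls of LS-Par replicates 1 and 2 had the lowest SD (1.48 and 1.53 units against 1.68 to 1.81 on the other arrays), and the 3 splits that join these arrays with an LS-3B array gave 96 to 216 such probes by the scanner flag but 18 to 51 under 1 intensity threshold for all arrays. Whether noise is the whole cause stays open. Under that threshold a ratio of 1.94 remained (281 against 145 probes, exact binomial interval 1.58 to 2.38, counting error only), over the 1.5 set beforehand as the bound against noise. That bound was too low, since 3 of the 9 pairs of mixed splits were as lopsided, up to 97 against 28 probes (a ratio of 3.46). Whether the scaling contributes stays open, since after quantile normalization the ratio was 1.56 with an interval of 1.28 to 1.90. A larger set of transcripts lost than gained in LS-3B cells is a hypothesis that was not tested further. The counts past the threshold do not favour it in every setting: 938 probes were lower and 863 higher in the main fit, but 927 and 935 with quantile normalization. They were 700 and 827 with normexp, and 709 and 845 with an offset of 50 added to the processed signal. The offset in both shrinks differences of dim probes, so these last counts say little against the hypothesis.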
